A study of Mus musculus with 9 samples.

How the data were processed

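RNA was measured by poly-A RNA sequencing in 9 libraries of mouse pancreatic stellate cells. These are fibroblast-like cells of the pancreas that store retinoids when quiescent and make matrix when activated. The cells were from C57BL/6 mice, had become immortal by spontaneous outgrowth, and carried lentiviral Cas9 with 1 guide RNA, followed by puromycin selection without cloning. The control guide targets R26, the Rosa26 locus commonly used as a neutral target, and the other guide targets Hif1a, which encodes the oxygen-regulated subunit of the transcription factor HIF-1. The labels give 3 groups of 3 libraries: R26 cells kept at 20% oxygen for 48 h (R26 normoxia), R26 cells kept at 0.5% oxygen for 48 h (R26 hypoxia), and cells with the Hif1a guide at 0.5% oxygen for 48 h (HIF1a-ko hypoxia). HIF1a-ko cells at 20% oxygen were not analysed here, so no interaction of oxygen and guide was fitted. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

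The deposited values are whole-number read counts per Ensembl gene, with no normalization. Per the submitters' processing notes, bcl2fastq 2.17, Trimmomatic, STAR, featureCounts and DESeq2 were used with the genome build GRCm38; the notes as used here give no roles, order or settings. The annotation release, the strand setting of the counting and the handling of reads that match several places are not given in the sources used here. Reads shared with near-identical copies, and reads from genes that overlap on the same or the opposite strand, could therefore have been lost or assigned to the wrong gene. Each column was matched to a sample by its name, and 1 column, R26 hypoxia 3, carries the same 4 parts as its sample title in another order. Of 49315 gene identifiers, 48970 were paired with a symbol in GENCODE M21 and 345 were not. The unpaired identifiers held 0.056% to 0.087% of the counts of a library, and 66 symbols belonged to more than 1 identifier.

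Total counts were 44664655, 43837809 and 88451200 in R26 normoxia 1 to 3, 47176142, 50912052 and 107840223 in R26 hypoxia 1 to 3, and 93471706, 51279104 and 48176260 in HIF1a-ko hypoxia 1 to 3. The 3 libraries with at least 88451200 counts are called deeper below, and the other 6 shallower. This split was made from the data and is not a group of the study. The number of genes with at least 1 count was 24622 to 26635 per library. The 10 most counted genes took 7.25% to 8.59% of the counts. A chi-square statistic per degree of freedom between libraries of a group was 6.73 to 69.9, so no 2 libraries agreed within sampling noise and all 9 were counted as samples.

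Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided), with TMM normalization, the filterByExpr filter, all 9 libraries in 1 fit and group as the only term. The filter left 18211 genes. P-values were adjusted by the Benjamini-Hochberg method over these genes, and genes with an adjusted p under 0.05 are called changed. Every adjusted p of a gene below comes from this test unless another is named. Expression is given as counts scaled to a common library size (CPM) with the TMM factors, as mean ± SD over the 3 libraries of a group. Log2 fold changes carry the standard error (SE) of the fit. Retained part means the CPM in HIF1a-ko hypoxia minus that in R26 normoxia, as a percent of R26 hypoxia minus R26 normoxia.

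The comparisons, their test, 23 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule names 26 genes in every comparison. It adds the 10 highest and 10 lowest log2 fold changes of the first 2 comparisons and the 5 and 5 of the third, among changed genes with an average log2 CPM of at least 3 and no overlap between groups. It adds up to 4 changed members of each list called by camera, and the 5 lowest and 5 highest retained parts. Predicted genes without a proper symbol were left out. Together this gave 149 genes. The rule's Ca9 was counted as Car9, its current mouse symbol. Ccl7, Sod2, Cd74, Lyz2, Saa3, Krt19, Muc1, Vwf, Kdr, Egfl7, Cpb1, Cela1, Ciita, Slc2a3, Eno2 and Pfkfb4 lie outside the rule and were named, to complete small counts, after their values were seen.

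Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the 23 lists of a comparison. Camera asks whether the members of a list rank higher or lower than the other genes. Each list was tested again with a correlation estimated from the data, and with fry. Fry asks whether the members of a list shifted, without setting them against the other genes. Counts of changed members are given over all genes tested, and also adjusted over the list alone. The results of 1 of the 23 lists are left out of the text.

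The 2 comparisons that share the R26 hypoxia libraries have correlated chance values. Their overlap, and the covariance and correlation of their log2 fold changes, were set against 20 simulations of unchanged groups, and the overlap also against that of independent lists. Pairing by replicate number was checked by correlating deviations from the group means. For hypoxia against normoxia all 3 same-numbered pairs correlated at 0.48 to 0.85, above the threshold of 0.1 set before, so the numbers were taken to pair these libraries. In both comparisons with HIF1a-ko hypoxia only 1 of 3 pairs passed, with correlations of -0.66 to 0.57 and of -0.67 to 0.59, and the numbers were not taken to pair them. The correlations follow depth, being 0.48 to 0.85 in the 15 pairs from different groups that share a depth class and -0.71 to -0.62 in the other 12.

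Alternatives were DESeq2 size factors, upper-quartile normalization, no filter, a stricter filter, DESeq2 1.42.0, limma-voom, edgeR with its legacy and robust settings, only the 2 groups compared, the replicate block, each library left out in turn, counts thinned to the smallest total, and a log2 fold change of at least 1. The depth class as a term, the 6 shallower libraries alone, and the 2 groups with the replicate block were added after the data were seen. Lists of colon epithelium, adipose tissue and plasma cell genes, with liver, skeletal muscle and brain genes as controls, were written after genes of the first 3 kinds had been noticed, leaving those out. Length and GC trends were fitted with mgcv 1.9.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Positions are those of GENCODE M21 on GRCm38, counted from 1. Shared sequence is the percent of a gene's words of 50 bases that occur in transcripts of other genes.

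The test was run on simulated counts with 200 changed genes at folds of 1.5, 2 and 4. It recovered 43.3%, 52.2% and 75.8% of them in the hypoxia against normoxia design, with 11.5% of 148 calls false. The HIF1a-ko against R26 hypoxia design gave 37.3%, 64.2% and 84.8%, with 7.89% of 152 calls false. The HIF1a-ko hypoxia against R26 normoxia design gave 35.8%, 59.7% and 86.4%, with 6.16% of 146 calls false. Between 17770 and 17793 genes were tested in these runs. The share of false calls thus lay above the nominal 5% in each. In the data 25.8% to 46.8% of the genes tested were called changed, a far larger part than the 200 simulated. The simulated libraries also had no depth classes, so neither the recovered nor the false shares need hold for the data. In each design camera called the list whose members had been moved, and it called 0, 0 and 1 of the other lists.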

Results

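The data are read counts of 9 poly-A RNA libraries of immortalised mouse pancreatic stellate cells, 3 for each of R26 normoxia, R26 hypoxia and HIF1a-ko hypoxia. Library totals ran from 43837809 to 107840223 counts, and 1 library of each group was sequenced more deeply than the others. The title of the series links hypoxia to an inflammatory state of fibroblasts. The design allows 3 comparisons: the response of control cells to low oxygen, the effect of the Hif1a guide in low oxygen, and what still differs from normoxia when the Hif1a guide and low oxygen are combined.

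The targeted gene, Hif1a (ENSMUSG00000021109, chromosome 12, 73901375 to 73947530, plus strand), was counted at 194, 192.4 and 224.8 CPM in R26 normoxia 1 to 3, at 177.8, 168.7 and 207.1 CPM in R26 hypoxia 1 to 3, and at 123.3, 116.9 and 125 CPM in HIF1a-ko hypoxia 1 to 3. It was lower in all 3 HIF1a-ko libraries than in all 6 R26 libraries, with a log2 fold change of -0.60 ± 0.09 (SE) against R26 hypoxia (adjusted p = 0.000319) and of -0.74 ± 0.09 against R26 normoxia (adjusted p = 9.95e-05). Between hypoxia and normoxia it differed by -0.14 ± 0.09 (adjusted p = 0.273, and adjusted p = 0.042 with depth class as a term). A Cas9 cut need not lower the transcript, so this level is only a weak check of the labels. Exons of Hif1a overlap Gm15283 on the other strand over 330 bp and Gm49321 on the same strand over 148 bp, and Hif1a shares 2.2% of its sequence with Gm49321.

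Within each group the deeper library stood apart. The first principal component held 43.8% of the variance and put the 3 deeper libraries at 51.8 to 79.8 and the 6 shallower ones at -48.5 to -24.2. The second (30.2%) separated HIF1a-ko from R26 cells and the third (12%) separated the oxygen levels of the R26 cells. Between the depth classes, 2406 genes were higher and 2880 lower in the deeper libraries. A set of 194 genes was at least 5 times higher in the shallower libraries at 1 CPM or more, among them the epithelial keratin Krt8 (18.8 against 0.0176 CPM), the colon gene Lypd8 (30.4 against 0 CPM), the immunoglobulin gene Igha (30.8 against 0 CPM) and the fat cell gene Adipoq (9.14 against 0.00375 CPM). These 4 were picked after their values were seen. The deeper class holds 1 library of each group, so each comparison below contains the same mix of depth classes. That mix does not make the levels of such genes equal between groups. In the shallower libraries Igha was at 25.9 and 11.5 CPM in R26 normoxia and at 42.8 and 46.9 CPM in HIF1a-ko hypoxia. It was at 19.1 and 38.9 CPM in R26 hypoxia, while Krt8 stood at 15.3 to 23.7 CPM in all 6.

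**Figure D1:**
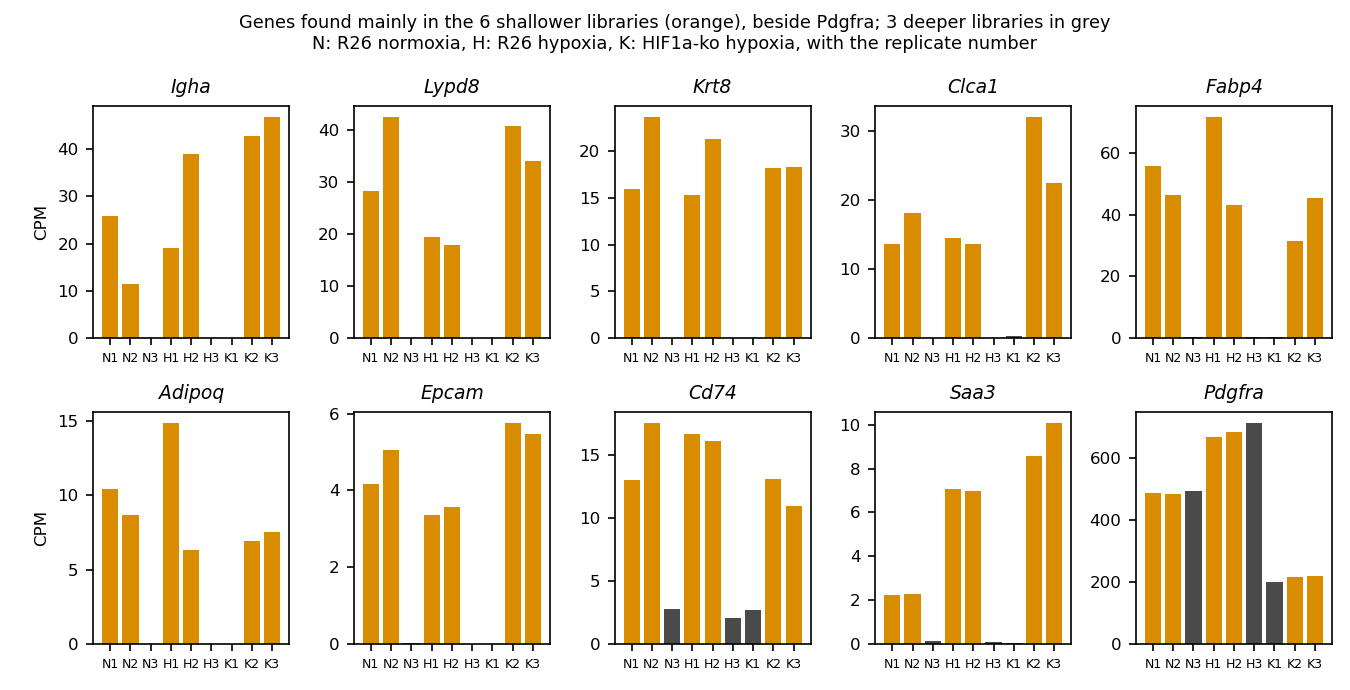
CPM per library (bars) of 9 genes found mainly in the 6 shallower libraries (orange) and of Pdgfra, with the 3 deeper libraries in grey and N, H and K for R26 normoxia, R26 hypoxia and HIF1a-ko hypoxia. Krt8 averaged 18.8 CPM in the shallower libraries and 0.0176 CPM in the deeper ones.

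In R26 cells, 48 h at 0.5% oxygen raised 18 of 21 glycolysis genes and 23 of 24 HIF targets. Egln3, a prolyl hydroxylase that marks HIF subunits for degradation, rose from 2.4 ± 0.825 to 41.2 ± 1.5 CPM (SD, n = 3 per group). Slc16a3, the lactate exporter MCT4, rose 9.93-fold from 28.1 ± 2.08 to 278.6 ± 18.3 CPM. Pdk1, which restrains the entry of pyruvate into mitochondria, rose 6.71-fold, and Vegfa, the angiogenic growth factor, rose 2.66-fold. Of 20 cholesterol synthesis genes 18 fell (list adjusted p = 0.0913 with an estimated correlation), and of 13 transcripts of the mitochondrial genome 8 fell.

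Of 24 HIF targets tested, 23 rose and none fell over all genes (23 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 1.49 (camera adjusted p = 2.06e-119). The other member, Stc2, stood at 1.08 ± 0.175 and 0.624 ± 0.365 CPM (adjusted p = 0.103 over all genes). Adm, a vasodilator peptide, rose by 3.06 ± 0.12 on the log2 scale, Ankrd37 by 2.93 ± 0.16 and Bnip3, a mitophagy receptor, by 2.72 ± 0.06. Bnip3 shares 21.9% of its sequence with other genes. Of 21 glycolysis genes, 18 rose and none fell by either count (median 1.65, camera adjusted p = 1.5e-146). Pgk1, phosphoglycerate kinase, rose 7.97-fold, Pfkl 6.51-fold, Ldha, lactate dehydrogenase A, 3.62-fold and Slc2a1, the glucose transporter GLUT1, 3.33-fold. Slc2a3, Eno2 and Pfkfb4 did not pass the test. Pgk1 shares 67.9% of its sequence with Pgk1-rs7, so its count is uncertain. Among 9 HIF pathway components only the hydroxylases Egln1 (log2 fold change 1.59) and Egln3 (4.18) and Vhl (0.19) rose (camera adjusted p = 4.26e-05), and the call for Vhl was lost without R26 normoxia 1. These 3 lists were also called with an estimated correlation. The HIF pathway list is not separate support, since Egln1 and Egln3 are also members of the HIF target list. Its median was 0.04.

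Genes that modify collagen rose as a group: 11 of 17 rose and none fell (12 and 1 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 4.23e-32). The prolyl hydroxylases P4ha2 and P4ha1 rose by 2.15 and 1.68 on the log2 scale, the lysyl hydroxylases Plod1 and Plod2 by 1.58 and 1.01, and the cross-linking enzyme Lox by 0.95. P4ha1, P4ha2 and Plod2 are also members of the HIF target list. Of 23 structural matrix genes 10 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.00663, and adjusted p = 0.326 with an estimated correlation). Col6a3 rose from 484.9 ± 13.6 to 816.3 ± 30.5 CPM, and Col1a1 stood at 5070.5 ± 489.2 and 6105.4 ± 546 CPM (log2 fold change 0.27, adjusted p = 0.0529, and called with the replicate block at adjusted p = 0.044 and by DESeq2 at adjusted p = 0.0114). Of 20 myofibroblastic markers 6 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.305). Acta2, the smooth muscle actin of activated stellate cells, fell from 1520.5 ± 30.2 to 786.5 ± 51.1 CPM.

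Of 25 markers of inflammatory fibroblasts 8 rose and 4 fell by either count (median 0.42, camera adjusted p = 0.0167, and adjusted p = 0.589 with an estimated correlation). Il6 rose 2.23-fold but remained low, from 1.15 ± 0.25 to 2.42 ± 0.33 CPM. Cxcl5 rose from 2.83 to 7.03 CPM, Ly6c1 from 14.7 to 44.3 CPM, and the complement gene C3 from 1421.8 ± 141.6 to 2141.4 ± 304.8 CPM. Cxcl12, a chemokine that stromal cells make, rose 1.33-fold. Ly6c1 shares 31.7% of its sequence with Ly6c2. The members that fell were the chemokines Ccl2 and Ccl7, the cytokine Lif and Sod2, and the call for Lif was lost without any 1 of R26 normoxia 1, R26 normoxia 3, R26 hypoxia 1 and HIF1a-ko hypoxia 3. Of 18 NF-kB and cytokine genes 6 rose and 4 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.305).

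Of 20 cholesterol synthesis genes 18 fell and none rose (19 fell adjusted over the list alone), with a median of -0.72 (camera adjusted p = 2.86e-24, and adjusted p = 0.0913 with an estimated correlation). Insig1, which holds back the sterol-responsive factor SREBP, fell from 135.8 ± 7.76 to 45.4 ± 1.89 CPM, and Msmo1 from 62 to 26.6 CPM. Of 13 mitochondrially encoded transcripts 8 fell and none rose by either count (median -1.11, camera adjusted p = 1.57e-19), and mt-Cytb fell from 2877 ± 48 to 852.4 ± 47.3 CPM. The mitochondrial share of all counts was 1.65% to 1.78% in R26 normoxia and 0.764% to 0.811% in R26 hypoxia. With other genes, mt-Co3 shares 99.9% of its sequence, mt-Nd4l 98.8% and mt-Nd4 62.2%, and mt-Nd3 shares most of its own. By contrast, mt-Nd2 shares 8.2% and mt-Nd5 7.6%, while mt-Cytb and mt-Nd6 share none. The mitochondrial share and the counts of changed mitochondrial transcripts, here and below, are therefore uncertain. Of 25 nuclear-encoded genes of oxidative phosphorylation 6 fell (7 adjusted over the list alone; median -0.22, camera adjusted p = 0.00557, and adjusted p = 0.589 with an estimated correlation). The list of oxidative phosphorylation, nuclear encoded, was no longer called without R26 hypoxia 3. Amino acid response genes fell in 9 of 19 cases and rose in 2 by either count (camera adjusted p = 0.000367, and adjusted p = 0.218 with an estimated correlation), among them the cystine transporter Slc7a11 (6.13 to 2.33 CPM). Of 18 p53 targets 7 fell and none rose by either count (camera adjusted p = 0.00672, and adjusted p = 0.14 with an estimated correlation). Cell cycle genes went both ways, with 3 of 25 higher and 9 lower (5 and 9 adjusted over the list alone). Their median was 0.07 while camera ranked them lower (adjusted p = 0.148).

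Interferon response genes differed between libraries of a group. Of 22 genes 3 fell over all genes and 1 adjusted over the list alone (median -0.74, camera adjusted p = 0.00572, adjusted p = 0.709 with an estimated correlation, and adjusted p = 0.0512 without R26 hypoxia 3). Ifit1 was at 43.6 to 64.9 CPM in R26 normoxia, and in R26 hypoxia at 71.7 CPM in library 1 but 8.16 and 8.22 CPM in libraries 2 and 3. Without R26 hypoxia 1 its log2 fold change was -2.68 (adjusted p = 6.81e-05), against -0.86 with it (adjusted p = 0.444). Of 16 matrix proteases 5 rose and 5 fell (7 and 6 adjusted over the list alone), of 16 endoplasmic reticulum chaperones 5 rose and 1 fell (6 and 1), and of 8 antigen-presenting markers none changed (camera adjusted p of 0.209, 0.269 and 0.863). Markers of leukocytes and acinar or islet cells held no changed gene, those of endothelial cells 1, Vwf, which fell from 4.75 ± 0.118 to 2.96 ± 0.267 CPM, and those of epithelial cells 2 that rose, Krt19 (19.2 ± 7.21 to 54.7 ± 11.6 CPM) and Muc1. The epithelial gene Krt19, the leukocyte gene Lyz2, the antigen-presenting gene Cd74 and the inflammatory marker Saa3 were lower in the deeper library of each group than in both shallower ones, while Muc1 averaged 1.98 CPM in the shallower and 2.25 CPM in the deeper libraries. Cd74 averaged 14.6 CPM in the shallower and 2.52 CPM in the deeper libraries.

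In all, 4697 of 18211 genes changed between R26 hypoxia and R26 normoxia, 2392 higher and 2305 lower, and 606 of them by a log2 fold change of at least 1 (395 higher, 211 lower). With the replicate number as a block in a fit of these 2 groups alone, 7398 genes changed, 3904 higher and 3494 lower. With depth class as a term 7092 changed.

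In low oxygen, cells with the Hif1a guide had less of the glycolytic and HIF target transcripts than R26 cells and more of the transcripts of cell division and amino acid supply. Pdk1 fell 10.1 times, from 299.8 ± 6.64 to 29.6 ± 1.25 CPM, and Slc16a3 fell 9 times, to 31 ± 0.698 CPM. The cystine transporter gene Slc7a11 rose 11.6-fold, from 2.33 ± 0.28 to 27.3 ± 1.85 CPM, and the replication helicase gene Mcm5 rose 6.57-fold, from 18.9 ± 1.71 to 124.6 ± 9.53 CPM. Among inflammatory markers, C3 fell 7.07 times, to 303 ± 24.6 CPM, and the fibroblast receptor Pdgfra fell 3.24 times.

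Of 24 HIF targets 19 fell and 1, Stc2, rose by either count (median -1.16, camera adjusted p = 1.86e-26). Egln3 fell to 5.28 ± 0.636 CPM and Bnip3 to 60.1 ± 3.26 CPM. Vegfa stood at 402.5 ± 35 CPM in R26 and 321.9 ± 12 CPM in HIF1a-ko cells (log2 fold change -0.32, adjusted p = 0.00874), a call lost without HIF1a-ko hypoxia 3 (adjusted p = 0.0512). Ero1l, an oxidase of the endoplasmic reticulum, stood at 166 ± 11 and 161.6 ± 3.44 CPM (adjusted p = 0.629). Of 21 glycolysis genes 20 fell and none rose by either count (median -1.25, camera adjusted p = 9.64e-41). Pfkl fell 6.74 times, Pgk1 3.92 times and Ldha 3.4 times. Of 9 HIF pathway components 6 fell and 1 rose by either count (camera adjusted p = 0.000724), with Egln1 at -1.78 on the log2 scale. All 3 lists were also called with an estimated correlation, with Egln1 and Egln3 again shared by the HIF target and HIF pathway lists.

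All 25 cell cycle genes rose by either count, with a median of 1.91 (camera adjusted p = 5.14e-59). Mki67, a marker of dividing cells, rose from 110.2 ± 15.1 to 402.9 ± 13.9 CPM, and Top2a, which untangles replicated DNA, from 90.7 ± 15.3 to 436 ± 13 CPM. Of 19 amino acid response genes 18 rose and 1, Cebpb, fell by either count (median 1.92, camera adjusted p = 5.85e-39). Slc7a5, a transporter of large neutral amino acids, rose from 30.6 ± 1.67 to 270.1 ± 31.1 CPM, Mthfd2, a mitochondrial folate enzyme, from 13.7 ± 1.08 to 113.6 ± 9.53 CPM, and Trib3 from 8.8 ± 0.745 to 61.7 ± 3.65 CPM. Both lists were also called with an estimated correlation. Of 18 p53 targets 12 rose and 2 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.000178, and called with an estimated correlation). Gdf15 was among the risers, while Cdkn1a, the cell cycle inhibitor p21, fell from 116.7 ± 1.68 to 86.7 ± 2.06 CPM.

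Of 25 inflammatory markers 9 fell and 3 rose (9 and 5 adjusted over the list alone; median -0.15, camera adjusted p = 0.0102, and adjusted p = 0.425 with an estimated correlation). Il6 fell to 1.02 ± 0.246 CPM, Cxcl5 to 2.89 CPM, and the interleukin-1 receptor gene Il1r1 from 100.5 ± 6.33 to 36.2 ± 2.1 CPM. Lif rose from 5.24 ± 0.762 to 12 ± 0.286 CPM, and Ptgs2 stood at 46.8 ± 6.98 and 56.4 ± 2.74 CPM (adjusted p = 0.0546, with Ptgs2 called by DESeq2 at adjusted p = 0.0256 and in the 6 shallower libraries at adjusted p = 3.96e-05). Of 18 NF-kB and cytokine genes 13 fell and 2 rose by either count (median -0.41, camera adjusted p = 3.09e-05, and called with an estimated correlation), with Tnfaip2 at -1.94 ± 0.09 and Bcl3 at -1.57 ± 0.09. Of 20 myofibroblastic markers 17 fell and 1, Acta2, rose by either count (median -0.60, camera adjusted p = 1.72e-09, and called with an estimated correlation). Thbs1 fell from 2873.3 ± 174.9 to 896.3 ± 49.5 CPM and Tnc from 2058.5 ± 88.8 to 779.4 ± 28.6 CPM. Of 23 structural matrix genes 13 fell and 4 rose by either count (camera adjusted p = 0.000835, and adjusted p = 0.18 with an estimated correlation). Fn1 fell from 15672.7 ± 292.2 to 8915.2 ± 106.5 CPM and Col1a1 to 3772.4 ± 185 CPM. Of 17 collagen modification genes 13 fell and 2 rose by either count (median -0.83, camera adjusted p = 7.96e-12, and called with an estimated correlation). Loxl1 stood at -1.49 and P4ha2 at -1.28 on the log2 scale.

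Genes of 4 other lists rose, each called by camera and not with an estimated correlation. Of 20 cholesterol synthesis genes 18 rose by either count (camera adjusted p = 1.09e-06, and adjusted p = 0.342 with an estimated correlation), Msmo1 to 69.7 CPM. Of 16 endoplasmic reticulum chaperone genes 11 rose and 2 fell by either count (camera adjusted p = 0.00068, and adjusted p = 0.152 with an estimated correlation), with Hspa5 at 772.7 ± 21.2 against 398.7 ± 9.92 CPM. Of 25 oxidative phosphorylation genes 17 rose (19 adjusted over the list alone; camera adjusted p = 0.000761, and adjusted p = 0.409 with an estimated correlation). Of 13 mitochondrially encoded transcripts 9 rose by either count (camera adjusted p = 0.000835, and adjusted p = 0.196 with an estimated correlation), mt-Cytb to 1524.1 ± 71.8 CPM. Outside the lists, the matrix protein gene Matn3 rose most by the naming rule, from 1.35 ± 0.2 to 24.3 ± 1.49 CPM, and Ndrg2, Tmem26 and Islr fell 8.78, 8.44 and 7.2 times. Of 22 interferon response genes 3 fell, and none adjusted over the list alone (camera adjusted p = 0.489). Without R26 hypoxia 1, Ifit3 (log2 fold change 0.59), Ifi44 (1.13) and Bst2 (0.54) were called higher. Of these only Ifit3 changed direction. Of 16 matrix proteases 4 rose and 6 fell (5 and 6 adjusted over the list alone), and of 8 antigen-presenting markers 1 (Ciita) fell (camera adjusted p of 0.255 and 0.834). Of the 4 lists of other cell types none was called by camera. Krt19, Muc1, the endothelial gene Vwf and the acinar genes Cpb1 and Cela1 fell, and the endothelial genes Kdr and Egfl7 rose.

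In all, 8514 genes changed between HIF1a-ko and R26 cells in hypoxia, 4119 higher and 4395 lower, and 2076 of them by a log2 fold change of at least 1 (1076 higher, 1000 lower). Because no HIF1a-ko normoxia libraries were analysed, a difference between these cell populations that was present at 20% oxygen cannot be separated from one that needs low oxygen.

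**Figure D2:**
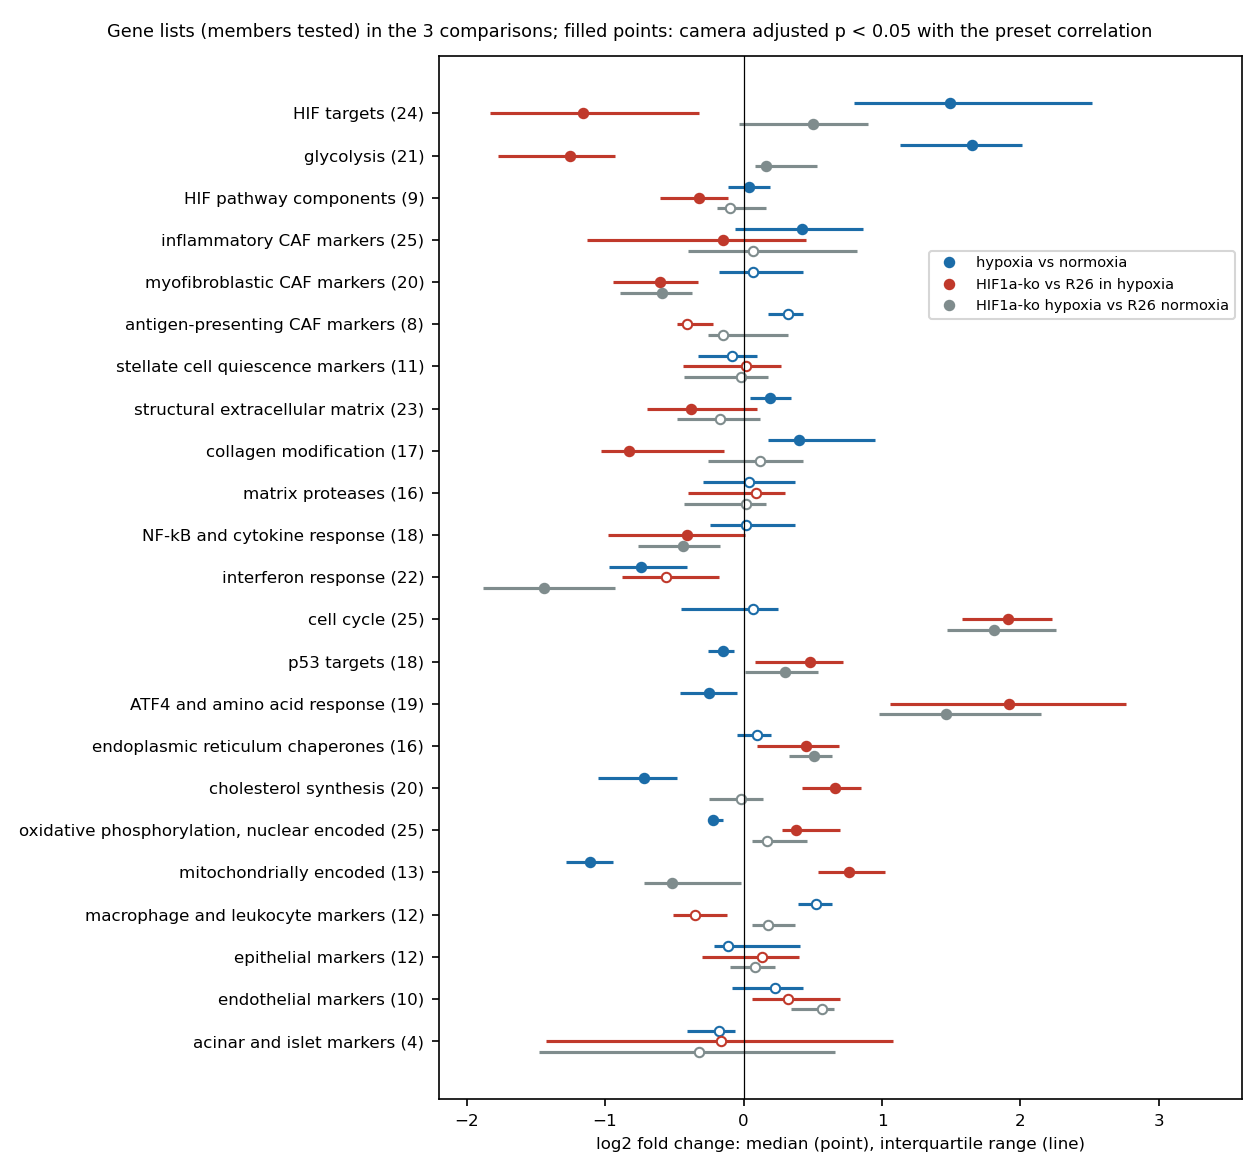
Median log2 fold change of each gene list (points) with its interquartile range (lines) in the 3 comparisons, with filled points for lists called by camera at the preset correlation. Cell cycle genes stand at 0.07 in hypoxia against normoxia and at 1.91 in HIF1a-ko against R26 cells in hypoxia, while glycolysis genes stand at 1.65 and -1.25.

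Against R26 normoxia, HIF1a-ko cells in hypoxia had more of the cell cycle and amino acid response transcripts. Most HIF targets were also higher than in R26 normoxia (14 of 24), while 5 were lower. Vegfa was 2.13-fold higher, at 321.9 ± 12 against 151.3 ± 14 CPM, and Ero1l rose by 1.56 on the log2 scale. Ldha (434.1 against 407.9 CPM, adjusted p = 0.348), Slc16a3 (31 against 28.1 CPM, adjusted p = 0.126) and Il6 (1.02 against 1.15 CPM, adjusted p = 0.634) did not pass the test. Mki67 was 4.93-fold higher, and Pdk1 fell below its normoxic level (29.6 against 44.7 CPM).

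Of 24 HIF targets 14 rose and 5 fell (17 and 6 adjusted over the list alone; camera adjusted p = 0.000658, and adjusted p = 0.259 with an estimated correlation). Of 21 glycolysis genes 9 rose and 4 fell by either count (camera adjusted p = 0.0367, and adjusted p = 0.79 with an estimated correlation), with Pgk1 2.04-fold higher. All 25 cell cycle genes rose by either count (median 1.81, camera adjusted p = 1.89e-65), and 17 of 19 amino acid response genes rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 1.05e-35), Asns from 57.7 to 283.7 CPM. Both lists were called with an estimated correlation. Of 20 myofibroblastic markers 15 fell and 2 rose by either count (camera adjusted p = 4.31e-09, and adjusted p = 0.0605 with an estimated correlation). Of 18 NF-kB and cytokine genes 12 fell and none rose (12 and 1 adjusted over the list alone; camera adjusted p = 0.000155, and called with an estimated correlation). C3 fell 4.69 times, Pdgfra 2.29 times and Il1r1 2.58 times, while inflammatory markers as a list, with 5 higher and 7 lower, were not called (camera adjusted p = 0.295). Of 16 chaperone genes 13 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 3.85e-06, and adjusted p = 0.108 with an estimated correlation). Of 18 p53 targets 9 rose and 3 fell by either count (camera adjusted p = 0.0367, and adjusted p = 0.259 with an estimated correlation). Of 13 mitochondrially encoded transcripts 7 fell and 1 rose by either count (camera adjusted p = 0.037, adjusted p = 0.608 with an estimated correlation, and adjusted p = 0.098 without HIF1a-ko hypoxia 1).

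Of 22 interferon response genes 15 fell and none rose (17 and none adjusted over the list alone; median -1.44, camera adjusted p = 0.00843, and adjusted p = 0.853 with an estimated correlation). Oas1a fell from 5.08 ± 0.891 to 1.13 ± 0.223 CPM, but it shares 57.6% of its sequence with Oas1g. The calls for Ifit1 (adjusted p = 0.0301) and Ifit3 (adjusted p = 0.0295) were lost without any 1 of 6 and of 5 single libraries. Not called by camera were HIF pathway components (2 higher, 4 lower), structural matrix (4, 9), collagen modification (7, 7), matrix proteases (4, 6), antigen-presenting markers (0, 0), cholesterol synthesis (1, 4), nuclear-encoded oxidative phosphorylation (5, 0) and markers of leukocytes (0, 0), epithelial (0, 0), endothelial (3, 1) and acinar or islet cells (0, 2). Adjusted over the list alone, collagen modification gave 8 and 8 and oxidative phosphorylation 3 and 0, and the others the same.

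In all, 7657 genes changed, 3628 higher and 4029 lower, and 1750 of them by a log2 fold change of at least 1. Oxygen and guide differ together in this comparison.

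Of the 4697 genes changed by hypoxia in R26 cells, 2789 (59.4%) were called in the opposite direction in HIF1a-ko hypoxia. With depth class as a term this was 4233 of 7092 genes, and at a log2 fold change of at least 1 it was 298 of 606. These were 1508 of the 2392 that rose (63%) and 1281 of the 2305 that fell (55.6%). A further shift in the same direction was called for 255 and 308 genes, where independent lists would share 541 and 556.3. Against R26 normoxia, 842 (35.2%) of the genes that rose and 960 (41.6%) of those that fell were still called changed the same way, while 570 and 473 were called beyond the normoxic level on the other side. For the genes shifted back, independent lists would share 577.3 and 521.3. Simulated unchanged groups gave a mean of 0 genes shifted back, and 1 at most, but such groups give almost no calls, so this does not measure what the shared libraries add to 2789. The covariance of the log2 fold changes was -0.16, against -0.096 in the simulations, a difference of -0.065, and their correlation was -0.42, against -0.5 in the simulations (-0.54 to -0.47). The simulated libraries had no depth classes, although the spread used for them included that difference, so the simulated covariance may be too large. A correlation near -0.5 is what a shared group of equal size gives for unchanged genes, so the correlations decide nothing. The R26 hypoxia libraries serve in both comparisons and are too few to be split, so part of the excess may come from these shared controls.

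Among genes with a log2 fold change of at least 1 and an average log2 CPM of at least 3, the 101 that hypoxia raised had a median retained part of 10.3% in HIF1a-ko cells (quartiles -3.95% and 25.8%). It was under 10% for 49 genes, below 0 for 30, and over 50% for 12. Slc16a3 retained 1.13% ± 0.502 (SE), Ldha 2.45% ± 2.14, Bnip3 4.37% ± 0.914, Slc2a1 19.2% ± 3.09, Vegfa 67.9% ± 6.2 and Ero1l 96% ± 5.77. The 48 genes that hypoxia lowered had a median of 46% (quartiles -14.9% and 78.8%), with 23 over 50%. Insig1 retained 71.2% ± 2.39 and mt-Cytb 66.8% ± 2.28 of the fall, and Scara5, a ferritin receptor, 105.4% ± 8.43. On GRCm38, Vegfa lies on chromosome 17 from 46016993 to 46032369, Slc16a3 on chromosome 11 from 120948480 to 120960868, Ldha on chromosome 7 from 46841475 to 46855627, and Ero1l on chromosome 14 from 45283087 to 45318771.

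**Figure D3:**
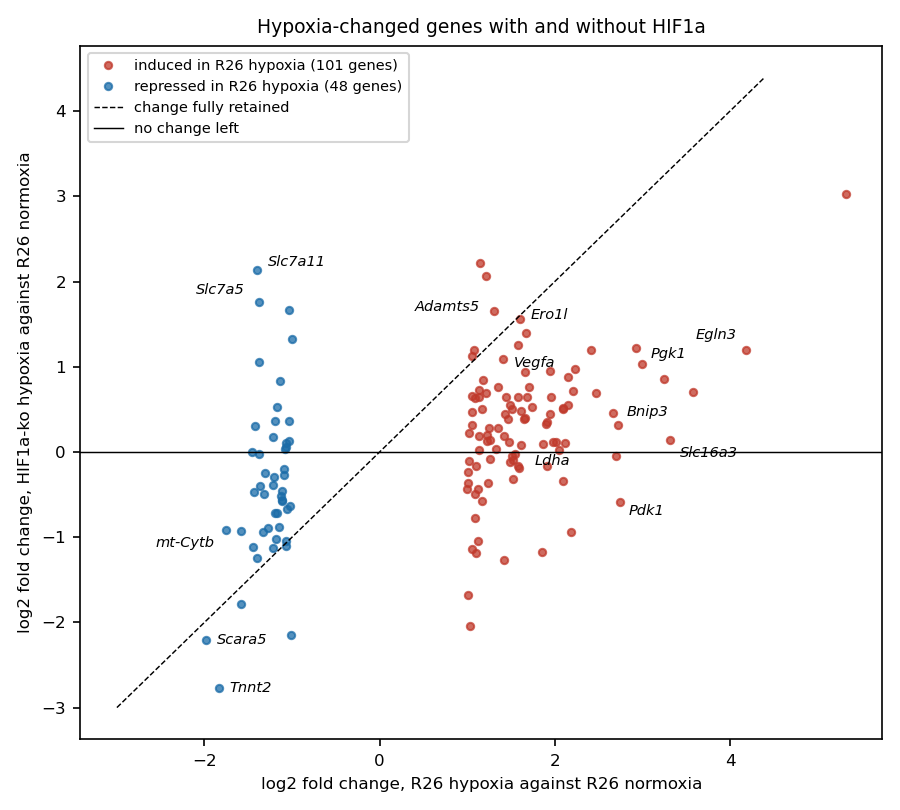
Log2 fold change of HIF1a-ko hypoxia against R26 normoxia (vertical axis) plotted against that of R26 hypoxia against R26 normoxia (horizontal axis), with each point 1 gene changed by hypoxia. Vegfa lies at 1.41 and 1.09, and Slc16a3 at 3.31 and 0.14.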

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

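The tests with depth class as a term, on the 6 shallower libraries alone, and on the 2 groups with the replicate block were chosen only after the data had been seen. With depth class as a term, hypoxia against normoxia called 7092 genes and 4233 genes shifted back, and Hif1a at -0.14 passed the test (adjusted p = 0.042). The replicate block in a fit of the 2 oxygen groups alone called 7398 genes. The replicate block in the fit of all 9 libraries called 4777, 8583 and 7745 genes in the 3 comparisons, 2881 genes shifted back and 37 gene list results, and left Hif1a at -0.14, -0.59 and -0.74. It changed no list call, and for hypoxia against normoxia it added the calls of Col1a1, Ccn2, Bub1 and Top2a and changed no other named gene. Requiring a log2 fold change of at least 1 left 606, 2076 and 1750 genes, and 298 shifted back. That loss follows from the added threshold. With an estimated correlation, 17 of the 37 gene list results called by camera remained. With fry 35 of the 37 remained, and 8 were called that camera had not called. The 2 lost were interferon response in hypoxia against normoxia (fry adjusted p = 0.164) and in HIF1a-ko hypoxia against R26 normoxia (fry adjusted p = 0.0698). Because fry does not set a list against the other genes, its calls do not check the ranking by camera. Without R26 hypoxia 1, Ifit3 in HIF1a-ko against R26 hypoxia turned to 0.59 (adjusted p = 0.0344), in a range over single left-out libraries of -1.37 to 0.59. For the other changes the cause was not tested.

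Leaving out 1 library at a time gave 3383 to 4538, 7440 to 8672 and 6555 to 8203 genes, 2158 to 2607 shifted back, and 35 to 38 gene list results. Hif1a then ranged from -0.23 to -0.05, from -0.66 to -0.51 and from -0.78 to -0.64. DESeq2 called 4897, 8333 and 7514 genes, and counts thinned to the smallest total 4577, 8330 and 7540. Over 21 settings, 9041 of 9372 values of named genes kept their direction and side of the threshold, 194 lost the call, 136 gained it and 1 reversed. Over 16 settings, fry among them, 1064 of 1104 gene list values did so, 25 lost the call, 15 gained it and none reversed. The median log2 fold change of all genes was -0.007, 0.001 and 0.011 with DESeq2 size factors and 0.001, -0.022 and -0.004 with upper-quartile normalization.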

Other observations

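Of the tests in this part, those on cells of other types, cells that escaped editing, depth class for Vegfa and Epas1 were chosen only after the results they measure had been seen. Some genes moved further in HIF1a-ko hypoxia than in R26 hypoxia, away from normoxia. The aggrecan-cleaving protease gene Adamts5 stood at 36.3 ± 1.23, 89.5 ± 1.42 and 113.5 ± 2.07 CPM in R26 normoxia, R26 hypoxia and HIF1a-ko hypoxia, a retained part of 145.2% ± 3.23 (SE), and Ptx3, a pentraxin of innate immunity, at 5.26 ± 0.419, 12.3 ± 1.03 and 22.2 ± 3.59 CPM. Among genes that fell, the chemokine gene Cxcl15 stood at 62.7 ± 0.682, 31.1 ± 0.318 and 14.2 ± 1.09 CPM and the troponin gene Tnnt2 at 18.4 ± 1.01, 5.21 ± 0.409 and 2.72 ± 0.336 CPM. Each of these 4 passed the edgeR test in all 3 comparisons. Prl2c2 shared 89.5% of its sequence with other genes and was left aside.

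Other genes were lower in R26 hypoxia than in both other groups. The cystine transporter gene Slc7a11 stood at 6.13, 2.33 and 27.3 CPM in R26 normoxia, R26 hypoxia and HIF1a-ko hypoxia, and the chromatin assembly gene Chaf1b at 6.13, 2.99 and 19.5 CPM. Interferon genes split within R26 hypoxia. Ifit3 was at 93.3, 65.5 and 62.8 CPM in R26 normoxia 1 to 3, at 77.1, 12.3 and 10.7 CPM in R26 hypoxia 1 to 3, and at 14.9, 19.3 and 17.6 CPM in HIF1a-ko hypoxia 1 to 3. Ifit3 shares 51.2% of its sequence with Ifit3b.

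The first pattern is that 1 library per group stood apart on the first principal component. Depth alone was argued against, since thinning to equal totals kept 0.95 of the share of the sum of squares on this contrast, and so was a trend with gene length and GC, which took 0.02 of the variance of the deeper to shallower ratio (0.1 at an average log2 CPM of at least 3). Wrong group labels were argued against by all 3 deeper libraries correlating best with the shallower libraries of their own group (r of 0.71, 0.73 and 0.82 across genes). Reads from colon epithelium, plasma cells and adipose tissue in the shallower libraries are a candidate source of part of the pattern. They would not account for the 2406 genes that were higher in the deeper libraries. Of the members of these 3 lists, 0.59 (12 of 18, 7 of 11 and 7 of 15) were at least 5 times higher in the shallower libraries at 0.1 CPM or more. For liver, muscle and brain genes the share was 0.09 (2 of 12, 1 of 10 and 0 of 10). In the deeper libraries 1, 0 and 5 members of the first 3 lists were at 1 CPM or more too. The summed CPM were 22 against 2.51 for colon, 6.27 against 1.08 for plasma cells and 718.4 against 615.7 for adipose genes, no biological explanation was tested, and how such reads entered stays open.

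The second pattern is the rise of cell cycle and amino acid response genes in HIF1a-ko hypoxia. The depth class as its source was argued against, since the 6 shallower libraries alone kept at least 0.99 of both medians (2.00 and 1.90). Each depth class holds libraries of every group, so a batch that ran with the guide was not tested. Leukocytes, epithelial cells or endothelial cells were argued against by their lists, whose highest median log2 fold change was 0.32, below the cell cycle median of 1.91 by more than the lists' own interquartile ranges of 0.39 to 0.7. That bound was set after the values were seen. The bounds set before, on the median level of each list, decided nothing, since these medians were 1.62, 2.42 and 1.49 CPM in HIF1a-ko hypoxia. Acinar or islet cells were argued against by their 12 listed genes, counted without the filter, of which the highest, Cela1, averaged 4.61 ± 0.36 CPM in HIF1a-ko hypoxia and the median gene 0.0414 CPM, while the cell cycle genes rose by a median of 55.8 CPM (first quartile 41.6 CPM). This replaced a bound on the interquartile range (2.51) of 4 genes, 3 of them under 1 CPM, that had left the question open, after earlier readings for and then against, and each reading was settled after the values were seen. Loss of HIF1a and another difference between these uncloned populations cannot be told apart. By the labels, all HIF1a-ko libraries carry the same guide and all R26 libraries another, so guide and population change together. With 0 HIF1a-ko normoxia libraries, whether the rise needs low oxygen also stays open.

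The third pattern is the part of the hypoxia response that HIF1a-ko cells retained. Cells that escaped editing, as the whole source, would give every induced gene about the same retained part. This was argued against by 40 of 101 induced genes lying under 10% by more than 2 SE while 9 lay over 50% by more than 2 SE. Escaped cells as part of the source stay open, since edited cells may shift the same genes on their own. The depth class was argued against as the whole source by Vegfa, which retained 59.5% in the shallower libraries and 87.6% in the deeper ones. A batch that ran with the guide was not tested here either. HIF-2 alpha acting in place of HIF1a may contribute, but Epas1, which encodes it, differed by 0.37 on the log2 scale (adjusted p = 0.686) at 4.71 CPM in the shallower and 1.42 CPM in the deeper libraries, and a transcript level does not measure the protein. A HIF1a-independent response thus stays a hypothesis that these libraries cannot decide.

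Of the 10 splits of the 6 libraries in each comparison, 1, the real one, called as many genes. The real splits called 4697, 8514 and 7657 genes and the highest of the other splits 0, 2 and 0. Each of the other splits mixes the groups compared, so a true difference adds to its spread and few calls follow. These 10 splits are also too few for a share under 0.05, so they do not decide whether chance made the calls.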
